A study of Mus musculus with 2 samples.

How the data were processed

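Total RNA sequencing was measured in 2 libraries of gastrocnemius muscle from male B6CASTF1/J mice, and the labels placed both in 1 group as biological replicates 1 and 2. Each library was made from 300 ng of RNA with ERCC spike-ins, which are synthetic RNAs of known composition, per the labels. Assembly mm10 and GENCODE annotation M21 are named per the labels and the list of files that came with each sample. The aligner and the quantification programs are not given in the sources used here. The column layouts are those that RSEM and kallisto write, but no header names the program or its version.

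The gene table and the first transcript table were derived by the authors from a transcriptome alignment, and the second transcript table directly from the sequencing reads, per the list of files that came with each sample. The deposited expected counts of the gene table and the first transcript table are reads per gene or transcript, with reads that fit several places shared out, per the file headers and the values. The estimated counts of the second transcript table have the same meaning, per the file headers. The deposited TPM values (transcript abundance scaled to a fixed total per library) divide by an effective length and sum to that total over all entries, spike-ins included, as the values show. The deposited FPKM values (fragments scaled by effective length and by depth) stand beside TPM in the first set, per the file headers. The deposited percent of isoform use gives each transcript's share of its gene's TPM, per the file headers. A deposited posterior standard deviation of each count, per the file headers, was used only to mark genes whose reads were shared with a near-identical gene. In the gene table the effective length was 99 nt below the length. In the second transcript table it was lower by a median of 344 nt in replicate 1 and 349 nt in replicate 2.

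Total expected counts were 40795740 in replicate 1 and 44919441 in replicate 2. The second quantification gave 39.87 M and 43.97 M estimated counts. Of the nonzero expected counts per gene, 83.8% were whole numbers within 0.001 in each library, and the others come from reads shared out between genes. Expected counts were rounded to whole numbers for every count test. Of the deposited entries, 55536 genes matched the annotation and were analysed. The 26248 tRNA entries, which held 1 and 2 expected counts, and the phiX entry were left out of the comparisons, and the 96 spike-ins were analysed separately.

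Genes were called detected at a TPM of at least 1 in both libraries. Replicate correlation was Pearson's r and Spearman's rho across genes of log2(TPM + 1), over genes with a TPM of at least 1 in either library, with a 95% interval from 1000 bootstrap draws of genes. The biological coefficient of variation (BCV), which is the spread between libraries beyond counting noise, was the square root of edgeR's common dispersion from an intercept-only design with TMM factors. A 2-sided exact binomial test compared each gene's rounded counts in replicate 2 with the sum of both, with the expected share from TMM library sizes, over the 14959 genes with a mean count of at least 10. A gene was called different at a Benjamini-Hochberg adjusted p below 0.05 and at least 2-fold. That test compares these 2 libraries and holds counting error only, so it says nothing of conditions. Gene fold changes use TMM-scaled counts + 0.5. Ratios printed with a counting interval, and lower bounds for a count of 0, leave out the added 0.5. edgeR's exact test with the common dispersion of the same libraries was an alternative. Its dispersion comes from the same difference that it tests, with 1 library on each side, so its p-values are not printed and it gives no replicate check. edgeR's quasi-likelihood test was not run, because the series has 1 group.

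The design fixed 37 gene lists, of which 23 name functions and 14 name cell types. For each, the median log2 ratio of replicate 2 to replicate 1 of TPM + 0.5 was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside the central 95% of its random lists was counted as different. Lists with fewer than 4 measured members were left out of that count. The percentile describes these libraries only. Of the list symbols, 1 (Cyr61) was not in the annotation under that name, and for 4 symbols with 2 gene IDs the ID with the higher mean was used.

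The named genes follow a rule fixed before the data were examined. They are the 10 nuclear protein-coding genes of highest mean TPM, and the 10 protein-coding genes highest in each library by fold among called genes with a mean count of at least 50. To these come the 2 to 4 most abundant members of each list with every called member, the sex-linked genes, and 20 genes named for their isoforms. Some genes that the rule takes are not reported here. Isoforms were compared between the quantifications in genes with a TPM of at least 10 and several transcripts.

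The statistics were tested on simulated data with fixed seeds. In counts drawn with Poisson noise for the binomial comparison of the 2 libraries, 0.014% of 14789 unchanged genes were called, as were 40% of 50 genes changed 2-fold, 96% of 50 changed 4-fold and 100% of 50 changed 8-fold. With the observed spread between libraries added, 3.61% of 14753 unchanged genes (533) were called. A simulated BCV of 0.2 was recovered as 0.197 over 14438 genes, and one of 0.4 as 0.39 over 14140 genes. Among 400 random lists of 15 genes drawn from 14959 genes, 4.5% fell outside the central range, and 100% of 100 lists shifted by a log2 of 0.5 lay above it. That check covers genes drawn at random only, and it says nothing of lists whose members vary together. The libraries were also compared as possible copies of 1 library: the chi-square over genes was 141 per degree of freedom, so both were kept as separate replicates.

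In all, 59 alternative settings were planned and 3 were added after seeing the data. They cover normalization, filters, pseudocounts, units, tests, denominators, the second quantification and leaving out each replicate. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 (size factors only), were used. No molecular identifiers are named in the sources used here, so intervals, exact tests and the limit of 3 counts for a count of 0 cover counting error only.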

Results

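Total RNA was sequenced from the gastrocnemius, the main muscle of the calf, of male B6CASTF1/J mice, hybrids of the C57BL/6J and CAST/EiJ strains, aged 18 to 20 months. The series holds 1 group with 2 libraries, so no comparison between conditions was possible. The comparisons below describe which genes made up the muscle's RNA, how far the replicates differed, and how far the deposited quantifications of the same reads differed. Replicate 1 held 40795740 expected counts and replicate 2 held 44919441. The labels call the libraries biological replicates and number their males differently but give both the same donor record, so whether the spread between them is between animals stays open. Each mean ± SD below is over n = 2 libraries.

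Genes of contraction, most of them on the fast-type list, and of its energy supply led the nuclear protein-coding genes. Skeletal actin Acta1 had the highest mean level, 19395 ± 1881 TPM (SD, n = 2), followed by the muscle creatine kinase Ckm at 18932 ± 4132 TPM and the fast troponin T gene Tnnt3 at 16785 ± 2286 TPM. The IIb myosin heavy chain Myh4 (ENSMUSG00000057003.12, mm10 chromosome 11, 67238029 to 67260446) had 13484 ± 3506 TPM. The fast regulatory light chain Mylpf had 12760 ± 3357 TPM, tropomyosin Tpm1 12583 ± 2316 TPM and the fast calcium pump Atp2a1 10966 ± 1633 TPM. Aldoa, the glycolytic aldolase of muscle, had 10125 ± 1271 TPM, Myl1 (fast essential light chain) 9642 ± 2915 TPM and Tnni2 (fast troponin I) 9090 ± 894 TPM. These 10 genes held 32.9% of nuclear protein-coding TPM in replicate 1 and 26.6% in replicate 2 (29.8 ± 4.44%), and 13.4% when every gene entry was in the denominator. The giant sarcomere gene Ttn took 9.32% and 8.23% of nuclear protein-coding counts. The second quantification gave higher TPM for each of the 10, for example 40369 TPM for Acta1. That does not by itself mean more reads. TPM shares out a fixed total, of which the short RNAs Rn7s1 and Rn7s2 took 28.7% and 22.7% in the first quantification. They took almost none in the second, which raises the TPM of other genes there. In all, 10959 genes, 10076 of them protein-coding, were detected at a TPM of at least 1 in both libraries.

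Short and mitochondrial RNAs took a large part of the rest. The signal recognition particle RNAs Rn7s1 and Rn7s2, identical copies whose reads cannot be divided between them, together held 28.7% of TPM in replicate 1 and 22.7% in replicate 2, but 4.47% and 3.51% of expected counts. The second quantification gave each of them 1.12 and 0 TPM. The 13 protein genes of the mitochondrial genome held 6.80% and 10.4% of TPM without mitochondrial rRNA and tRNA (8.60 ± 2.54%). They were led by mt-Co1, a cytochrome oxidase subunit, at 12971 and 19428 TPM. The mitochondrial rRNAs took 7.87% and 11.1% of all counts. The share of the 13 genes was 15.2 ± 3.92% when 4 pseudogenes on chromosome 1 that share reads with them (Gm28661, Gm10925, Gm28437 and Gm29216) were counted in, an alternative added after seeing the data.

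The fast IIb myosin dominated both libraries, and replicate 2 held more of the other adult chains, the fast IIx and IIa chains among them. Of the TPM of the 4 adult myosin heavy chains, Myh4 (IIb) held 95.1% in replicate 1 and 81.1% in replicate 2 (88.1 ± 9.91%). Myh1 (IIx) held 3.04% and 8.63%, Myh2 (IIa) 1.66% and 7.97%, and Myh7 (the slow type I chain, chromosome 14, 54970684 to 54994626) 0.175% and 2.30%. Of the fast-type sarcomere list's 15 members, 2 were called higher in replicate 2, Myh1 by 2.20-fold and Myh2 by 3.73-fold, and 0 were higher in replicate 1 by the exact binomial test. The most abundant members lay lower in replicate 2 without reaching 2-fold: Tnnt3 had 18401 and 15168 TPM, Mylpf 15133 and 10386 TPM and Tpm1 14220 and 10945 TPM. The list's median log2 ratio was -0.38, at percentile 0 of its matched random lists, and its mean -0.15, at percentile 1.5. Here and in every list below except the brown adipocytes, the counts adjusted over the list alone were the same as those over all genes tested.

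Every member of the slow-type sarcomere list was higher in replicate 2. All 15 of 15 passed the exact binomial test. The slow regulatory light chain Myl2 (chromosome 5, 122100951 to 122113472) had 40.02 and 564 TPM, 14.4-fold higher in replicate 2. Myl3 was 9.60-fold, Myh7 9.97-fold, and Tnnt1, Tnni1 and Tnnc1, the slow troponins, 11.5-fold, 13.9-fold and 10.5-fold higher. Csrp3, a Z-disc protein of slow and cardiac muscle, had 5.50 and 162 TPM, 28.3-fold higher. Mybpc1 (5.27-fold), Tpm3 (6.93-fold), the slow calcium pump Atp2a2 (7.08-fold), Myoz2 (8.97-fold), Ankrd2 (12.98-fold), Casq2 (4.27-fold) and Myh7b (11.1-fold) were also higher. Sarcolipin (Sln), a regulator of the calcium pump, had 3 and 17 counts, a ratio of 5.0 with a counting interval from 1.45 to 26.6. The list's median log2 ratio was 3.30, a 9.82-fold difference, at percentile 100.

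**Figure D1:**
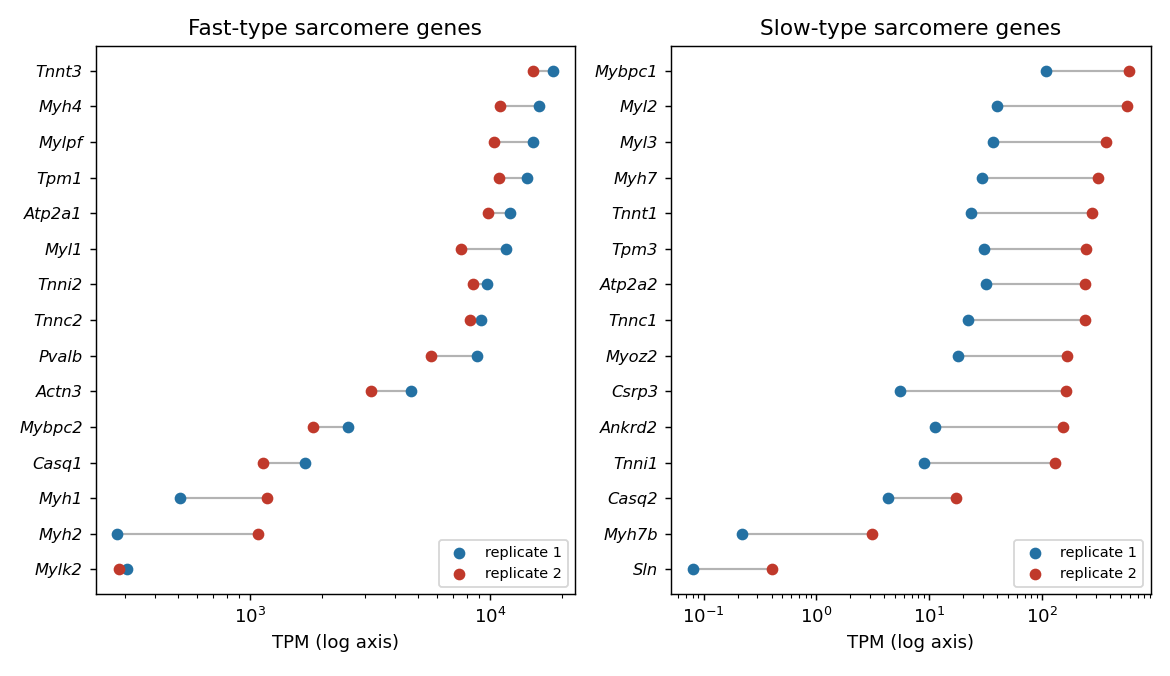
TPM (log axis) of each of the 15 fast-type and 15 slow-type sarcomere genes in replicate 1 (blue) and replicate 2 (red), with a grey line joining the 2 libraries of a gene. Each slow-type gene lies to the right in replicate 2, whereas 13 of the 15 fast-type genes lie to the left.

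Other muscle lists held mixed or small differences. Of 18 sarcomere genes shared by fibre types, 1 was called: Actn2, an alpha-actinin of the Z-disc, was 4.94-fold higher in replicate 2 (124.5 and 630 TPM). Acta1 (20725 and 18065 TPM), Neb (2479 and 2238 TPM) and Ttn (2170 and 2061 TPM) were not, and the list's median log2 was 0.03. Of 9 measured embryonic and neonatal genes, 2 were higher in replicate 2, embryonic myosin Myh3 (2.16-fold) and Tnnt2 (2.10-fold), and 2 were higher in replicate 1, cardiac actin Actc1 (4.62-fold) and the myogenic factor Myog (2.91-fold). That list's median was 0.12 and its mean -0.18, and Myh8 had 158 and 108 TPM. All 17 excitation-contraction genes had a log2 ratio below 0, none past the threshold, with Ryr1, the calcium release channel, at 850 and 731 TPM and Trdn at 695 and 584 TPM. That list's median was -0.22, at percentile 0.115. With spike-in scaling, which raises every gene's ratio alike, it was -0.039, so the signs depend on the scaling. Of 18 denervation and junction genes, Dach2 (4.44-fold) and Sln were higher in replicate 2 and Myog in replicate 1, while Hdac4 (31.9 and 27.3 TPM) and Musk (24.4 and 18.6 TPM) were not called (median -0.018, mean 0.0077). The shared list lay inside its random range, as did the embryonic and denervation lists in the main analysis. The embryonic list lay above with TMM-scaled counts (0.24) and the second quantification (0.23) and below with the mean (-0.18), and the denervation list below at a mean count of at least 100 (-0.11).

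The medians of the fat use and glycolysis lists lay on opposite sides of their random ranges, although most of their members did not pass the test. Of 21 fatty acid genes, 20 had a log2 ratio above 0, and 4 were called higher in replicate 2: the fatty acid binding protein Fabp3 (137 and 507 TPM, 3.57-fold), lipoprotein lipase Lpl (2.63-fold), the transporter Cd36 (2.21-fold) and the dehydrogenase Acadl (2.17-fold). Lpl, Cd36 and Acadl lost the call with edgeR's exact test. The fatty acid list's median log2 was 0.76, at percentile 100. Of 28 nuclear oxidative phosphorylation genes, 27 were above 0 and none was called, with Atp5b at 1191 and 1455 TPM and Cox6a2 at 518 and 856 TPM (median 0.33, percentile 100). All 13 mitochondrial-encoded protein genes were above 0 with none called (median 0.58, percentile 100), for example mt-Cytb at 8358 and 11885 TPM. Of 20 glycolysis and glycogen genes, 16 were below 0. The glycogen branching enzyme Gbe1 alone was called, 2.64-fold higher in replicate 2, and it lost the call with edgeR's exact test. Aldoa had 11024 and 9226 TPM, Gapdh 4474 and 3573 TPM and the glycogen phosphorylase Pygm 4425 and 3029 TPM (list median -0.37, percentile 0, mean -0.17). Of 7 creatine and phosphate buffer genes none was called (median -0.27, percentile 0.68), with Ckm at 21854 and 16010 TPM and the mitochondrial creatine kinase Ckmt2 at 341 and 636 TPM. With the mean in place of the median, neither nuclear oxidative phosphorylation (0.35) nor the creatine list (-0.14) lay outside its random range.

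The medians of the early response and heat shock lists lay above their random ranges. Of 22 immediate early genes, 13 were called higher in replicate 2 and 1, the mRNA decay factor Zfp36, in replicate 1 (2.28-fold). The stress factor Atf3 (ENSMUSG00000026628.13, chromosome 1, 191170296 to 191218039) had 1.92 and 68.9 TPM, 33.3-fold higher, and the AP-1 gene Fos 1.41 and 29.5 TPM, 21.7-fold higher. Fosb (7.42-fold), Egr3 (6.65-fold), Egr1 (5.42-fold), Nr4a3 (3.65-fold), Btg2 (3.48-fold), Egr2 (3.14-fold), Socs3 (2.91-fold), Jun (2.67-fold), Dusp1 (2.48-fold), Myc (2.43-fold) and Jund (2.02-fold) were also higher, while Nr4a1 had 82.8 and 98.8 TPM. The list's median log2 was 0.96, at percentile 100, and with a pseudocount of 5 it was 0.29, at percentile 100 as well. edgeR's exact test called 7 and 0 of these genes. Of 17 heat shock genes, 6 were called higher in replicate 2 and 0 in replicate 1 (median 0.55, percentile 100). That median was 0.31 with TMM-scaled counts and 0.35 in the second quantification, and the mean was 0.94, all above the random range. They were the small heat shock genes Hspb7 (11.9-fold), Hspb6 (3.27-fold) and Cryab (2.85-fold), the inducible Hspa1a (6.98-fold) and Hspa1b (4.54-fold), whose reads overlap, and Ddit3 (2.32-fold). Hspa8 had 610 and 634 TPM.

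Of 17 atrophy and proteolysis genes, 5 were called higher in replicate 1 and 1 in replicate 2. Ddit4, an inhibitor of mTORC1 signalling (ENSMUSG00000020108.4, chromosome 10, 59949669 to 59951834), had 85.1 and 3.41 TPM, 25.8-fold higher in replicate 1. Myostatin (Mstn, 2.19-fold), the metallothioneins Mt1 (2.14-fold) and Mt2 (2.23-fold) and the transcription factor Foxo1 (2.09-fold) were higher in replicate 1, and the autophagy gene Gabarapl1 was 2.32-fold higher in replicate 2. With spike-in scaling, and with edgeR's exact test, Ddit4 alone of those 5 was called, and edgeR did not call Gabarapl1. The muscle ubiquitin ligases Trim63 (176 and 136 TPM) and Fbxo32 (121 and 102 TPM) and the autophagy receptor Sqstm1 (254 and 255 TPM) were not called. The list's median was -0.12, at percentile 1.15. With a pseudocount of 5 it was -0.071, inside its random range, while the mean (-0.38) and the second quantification (-0.22) lay below theirs. With spike-in scaling, which raises every gene's ratio alike, the median was 0.073. Of 12 inflammation and interferon genes none was called (median -0.30, percentile 0), with B2m at 67.4 and 54.0 TPM and H2-K1 at 42.7 and 24.3 TPM. With no filter on low counts that list's median was -0.026, inside its random range, and with a pseudocount of 5 it was -0.068, below it.

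Of 16 clock genes, Per1 was called, 2.08-fold higher in replicate 1, while Tef had 77.2 and 52.5 TPM and Nr1d1 44.2 and 53.3 TPM (median -0.0012). Of 18 extracellular matrix genes, the proteoglycan Bgn was 2.06-fold higher in replicate 2, with Sparc at 93.4 and 84.3 TPM and Col3a1 at 48.2 and 30.5 TPM (median -0.025, mean 0.038). Of 11 histone genes, Hist2h2aa1 had 0 and 33 counts, at least 9.71-fold higher in replicate 2, but its reads are shared with near-identical copies and the second quantification gave 97.3 and 130.4 TPM. Hist1h1c had 72.1 and 66.2 TPM (list median 0.18). Of 11 long non-coding RNAs, Rian was 2.00-fold higher in replicate 1, with Rn7sk at 12920 and 15718 TPM and Rpph1 at 2489 and 2462 TPM (median -0.016), but 0 and 0 and 1.03 and 0 TPM in the second quantification. None of 25 cytosolic ribosomal genes (Rplp1 579 and 616 TPM, list median 0.09) and none of 12 reference genes (Actb 256 and 246 TPM, Ppia 116 and 102 TPM, median -0.029) was called. The sex-linked genes Ddx3y (28.8 and 28.7 TPM), Eif2s3y (20.2 and 21.2 TPM), Uty (5.99 and 5.56 TPM) and Kdm5d (3.46 and 3.50 TPM) were expressed in both libraries, which the labels call male (list median 0.0038). Each list of these 7 lay inside its random range, but the clock list lay below it with the mean (-0.14).

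The medians of the vessel, nerve and tendon marker lists lay above their random ranges, although most of their members did not pass the test. Of 12 endothelial genes, Kdr (2.13-fold) and Cldn5 (2.17-fold) were called, with Fabp4 at 72.8 and 94.97 TPM and Cdh5 at 13.2 and 17.0 TPM (list median 0.35, percentile 99.9). Of 12 smooth muscle and pericyte genes, the potassium channel gene Kcnj8 (2.25-fold) and Cnn1 (2.01-fold) were called, with Rgs5 at 59.6 and 79.2 TPM (median 0.49, percentile 99.98). Of 11 Schwann cell genes, Prx (2.07-fold), Ncmap (2.03-fold) and Sox10 (2.41-fold) were called, and the myelin gene Pmp22 had 9.55 and 14.2 TPM (median 0.43, percentile 99.8). None of 10 tendon genes was called (median 0.40, percentile 99.8), with Fmod at 33.2 and 45.0 TPM and Thbs4 at 25.02 and 40.7 TPM. Of 5 neutrophil and mast cell genes, Mcpt4 was 2.02-fold higher, and Tpsb2 had 1.29 and 2.46 TPM (median 0.53, percentile 98.2). Of 5 brown adipocyte genes, Dio2 was 2.71-fold higher, and Cidea as well when adjusted over the list alone, 2 against 1. Ppargc1a, a regulator of mitochondrial genes, had 15.7 and 22.4 TPM (median 0.50, percentile 99.5). Cox8b, a further member, was counted among the oxidative phosphorylation genes too. The brown adipocyte list's summed TPM was 877 and 965, with a median member at 0.24 and 0.67 TPM. Which cells its members came from was not tested. None of the member calls in these lists held with edgeR's exact test. The call of the brown adipocyte list was lost under 4 alternatives: pseudocount 0.1 (0.62), TMM-scaled counts (0.67), the mean (0.43) and the second quantification (0.30). That of the mast cell list was lost with no filter (0.096) and the mean (0.34), and that of the tendon list with the mean (0.31). With a pseudocount of 5 the medians were smaller but still above their random ranges: 0.20 for endothelial, 0.32 for smooth muscle, 0.09 for Schwann cell, 0.21 for tendon, 0.13 for mast cell and 0.11 for brown adipocyte genes. The Schwann cell median was 0.69 with pseudocount 0.1 and 0.83 with TMM-scaled counts, and the brown adipocyte median 0.29 with no filter.

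The remaining cell type lists lay inside their random ranges or were too small to place, though the fibroblast (0.16) and white adipocyte (0.18) lists lay above with TMM-scaled counts, and the erythrocyte list with no filter (0.24) and the second quantification (0.27). Members of the white adipocyte list were split (median 0.18). Higher in replicate 2 were the carbonic anhydrase Car3 (161 and 611 TPM, 3.66-fold), Adipoq (2.26-fold) and Lep (2.89-fold). Higher in replicate 1 were the lipogenic Fasn (2.70-fold), Thrsp (2.08-fold) and Retn (2.39-fold). Adipoq, Fasn, Thrsp and Retn lost the call with edgeR's exact test, so no call on the replicate 1 side held there. Car3 held most of the list's summed TPM (279 and 704), and which cells it came from was not tested. No member was called among 9 satellite cell genes (Sdc4 25.7 and 32.6 TPM, Cdh15 7.60 and 6.81 TPM, median 0.28) or 12 fibroblast genes (Gsn 252 and 242 TPM, Dcn 139 and 159 TPM, median 0.10). Nor was any called among 11 macrophage genes (Lyz2 16.9 and 20.4 TPM, median 0.06) or 7 erythrocyte genes (Hba-a1 138 and 168 TPM, Hbb-bs 130 and 171 TPM, median 0.29). Lymphocyte genes had 2 measured members, Ighm (81.2 and 54.3 TPM) and Jchain (0.14 and 0.27 TPM). Keratinocyte genes had 3, with Krt10 at 1.11 and 1.09 TPM and Perp at 0.89 and 0.66 TPM, and bone and cartilage genes had 3, with Alpl at 4.21 and 9.67 TPM and Col2a1 called 2.68-fold higher in replicate 1. Over all lists, 18 of 34 lay outside the central 95% of random lists, 12 higher in replicate 2 and 6 higher in replicate 1. For lists of genes drawn at random, 1.7 would be expected. Members of a fixed list can vary together and some lists share genes. The 18 are therefore not separate differences, and 1.7 is not the rate expected for such lists.

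**Figure D2:**
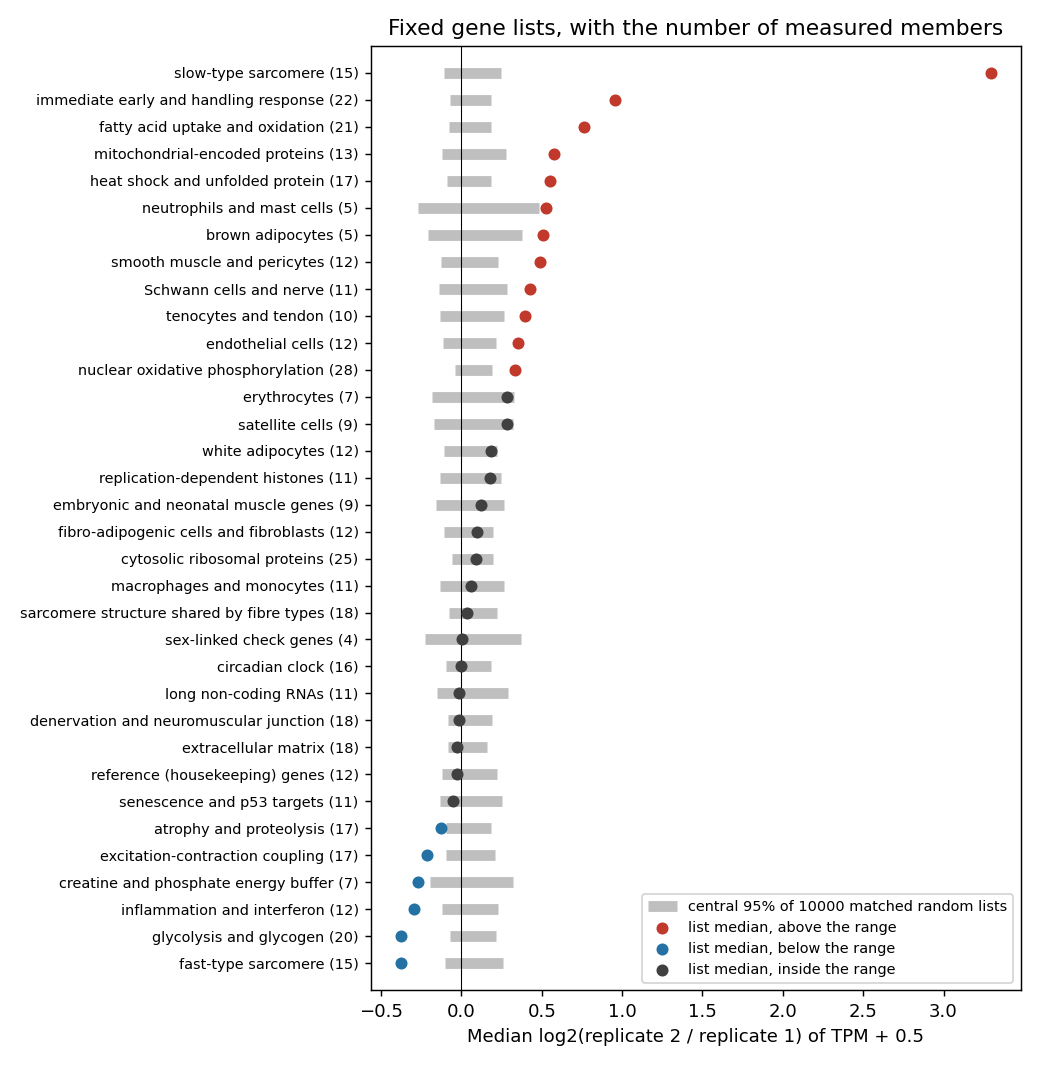
Median log2 ratio of replicate 2 to replicate 1 (TPM + 0.5) of each of 34 gene lists, with the number of measured members in brackets and the central 95% of 10000 matched random lists as a grey bar. Red points (12 lists) lie above the bar and blue points (6 lists) below it, and the slow-type sarcomere list at 3.30 stands farthest from its bar.

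Across all genes, 924 of 14959 differed beyond counting noise by at least 2-fold, 669 higher in replicate 2 and 255 higher in replicate 1 (72.4% higher in replicate 2), and 728 of them were protein-coding. Liver albumin, Alb, stood first with 1 and 756 counts, a ratio of 667 with a counting interval from 119 to 26400, and Apob, the lipoprotein of liver and gut, had 0 and 191 counts, at least 56.2-fold higher in replicate 2. Besides Atf3, Csrp3, Fos and Myl2, the genes highest in replicate 2 were Tbx1 (17.3-fold), Cyfip2 (14.2-fold), the M-band gene Myom3 (13.9-fold) and Gm28635, which had 0 and 151 counts, at least 44.4-fold in the gene table. Its reads are shared, and the second quantification gave 1.57 and 3.41 TPM, a log2 ratio of 1.16. Besides Ddit4 and Actc1, those highest in replicate 1 were the mitochondrial carrier Slc25a25 (131 and 20.1 TPM, 6.91-fold), Slc1a2 (7.54-fold by counts but 0.29 and 0.23 TPM), H2-Q6 (6.77-fold), the acetylcholine receptor subunit Chrna9 (6.64-fold), Themis3 (5.57-fold), Mettl21e (4.59-fold) and Htra4 (4.55-fold). Fam177a also stood there, with 108 and 1 counts, a ratio of 122 (counting interval 21.5 to 4880). The deposited posterior SD exceeded its counts, however, and the second quantification gave 4.11 and 4.59 TPM. In simulated counts with the observed spread between libraries, the binomial rule called 3.61% of unchanged genes, 533 of 14753. A single called member therefore says little about its list as a whole. The edgeR exact test, with a common dispersion from the same 2 libraries, called 319 genes, 250 and 69. With 1 library on each side neither test has a replicate check, so this count compares each gene with the usual difference between these libraries. Of the 74 called list members named here it called 36. Those that lost the call with spike-in scaling, 9 in all, were higher in replicate 1: Mstn, Mt1, Mt2, Foxo1, Zfp36, Per1, Thrsp, Col2a1 and Rian. Rian lost it under each of 5 alternatives, and Hist2h2aa1, Cldn5, Cnn1 and Mcpt4 in the second quantification. Among those that lost it with edgeR's exact test were also Myh1, Sln, Myh3, Tnnt2, Ddit3, Bgn, Per1 and Col2a1. Spike-in scaling, which shifted the median log2 of all genes to 0.23, called 1057 and 167 (86.4%).

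**Figure D3:**
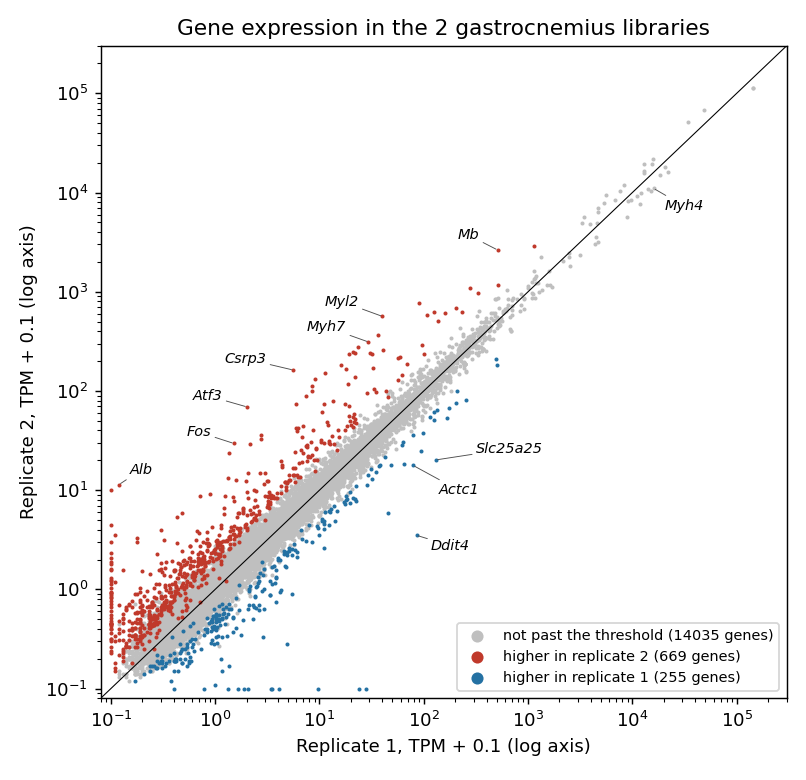
TPM of each of the 14959 tested genes in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes after adding 0.1. Red points are the 669 genes called higher in replicate 2 and blue points the 255 called higher in replicate 1, the black line marks equal TPM, and Alb, Atf3, Fos and Csrp3 lie far above it and Ddit4 far below.

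Across all genes the libraries were closely correlated. Pearson's r of log2(TPM + 1) was 0.973 (95% bootstrap interval 0.971 to 0.976) and Spearman's rho 0.968 across 11831 genes, which are not independent replicates. The BCV was 0.21 over 14307 genes. Over the 44 spike-ins with a mean count of at least 10 it was 0.0288. Spike-ins carry no difference between muscle samples, but their filter differed from that of the genes and no TMM factors were used. Spike-ins took 0.537% of counts in replicate 1 (Wilson 95% interval 0.534 to 0.539) and 0.474% in replicate 2 (0.472 to 0.476), so that replicate 2 held 1.13 times the gene counts per spike-in count. The 27 spike-ins with a mean count of at least 100 had a median absolute log2 ratio of 0.083 between the libraries, against 0.16 for 10236 genes in the same range of counts.

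The deposited quantifications of the same reads assigned many genes' reads to different transcripts. Of the 19 muscle genes chosen for their isoforms that have several transcripts, 12 had the same most abundant transcript in both quantifications and both libraries. Transcript ENSMUST00000032974.12 of Atp2a1 held 99.6 ± 0.403% of its gene's TPM in the first and 99.9 ± 0.0592% in the second, and ENSMUST00000179893.8 of Ryr1 held 96.3 ± 0.304% and 91.1 ± 0.253%. Myl1 was assigned mainly to ENSMUST00000119429.7 in the first (74.5 ± 0.99%), whereas ENSMUST00000186202.6 led in the second (41.5 ± 4.91%). ENSMUST00000074187.12 of Tnnt3 held 40.5 ± 5.71% in the first and 0.000729 ± 0.00103% in the second. In Ppargc1a the leading transcript differed between the libraries in both quantifications. Its transcript ENSMUST00000127135.2 held 36.9% and 25.9% in the first and 42.0% and 21.6% in the second. Across 3967 genes, 2738 (69.0%, Wilson 95% interval 67.6 to 70.4) had the same leading transcript in all tables. Within a library, r between the quantifications was 0.549 and 0.543 across transcripts (28417 and 28425) and 0.868 and 0.87 across genes, and neither transcripts nor genes are independent replicates.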

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

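No test was run on the values in this part, so none was chosen after the result was seen. Reads of phiX, the control DNA added to sequencing runs, stand outside the comparisons. The second quantification gave phiX 184 estimated reads in replicate 1 and 362 in replicate 2, above the limit of 3 counts that a count of 0 allows. The gene table gave 1 and 0 counts for the same entry.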

How the results depend on the processing

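The BCV without 3 lists, the mitochondrial share with pseudogenes and the lists under spike-in scaling were tests chosen after the result was seen; the others were planned. Detected genes numbered 6677 at a TPM of at least 5, where fewer genes can pass. The replicate correlation was 0.955 with pseudocount 0.1, 0.991 with no filter, 0.952 at a TPM of at least 10 and 0.976 for protein-coding genes. The BCV was 0.231 with no filter, 0.204 at a mean count of at least 100 and 0.199 without the slow-type, immediate early and fatty acid lists. Genes called different numbered 367 at a mean count of at least 100, where fewer are tested, 5299 with no fold threshold and 319 with edgeR's exact test, whose dispersion comes from the same 2 libraries. The mitochondrial protein share was 6.00% in expected counts, 12.5% in the second quantification and 15.2% with the pseudogenes. The top 10 genes held 22.7% in counts and 13.4% over all gene entries. The spike-in share was 0.85% in TPM and 0.37% in the second quantification. The correlation between quantifications was 0.317 with pseudocount 0.1, 0.785 with no filter and 0.202 at a TPM of at least 10. The same leading transcript was found in 66.1% of genes at a TPM of at least 1, and in 73.4% to 74.3% with 1 replicate left out, where fewer tables must match. Fam177a reversed to a log2 of 0.20 in the second quantification. By arithmetic, the near absence of Rn7s1 and Rn7s2 in the second quantification raises the TPM of other genes there. Elsewhere the cause was not tested. The Myh4 share was 84.8% to 88.5% in the other units, gene sets and quantification, and the number of differing lists 15 to 20. Of 100 values for the 20 genes of largest fold 99 kept the call; of 369 for 74 called list members 315 did and 54 lost it, 38 of these with edgeR; of 236 list medians 216 stayed inside or outside their random range, 11 lost the call, 9 gained it and 16 changed sign. DESeq2, total-count and spike-in scaling move all genes alike, and by little beside the folds of those 20 genes. Calls of the 20 that were kept there say nothing. Gm28635 kept its call although its log2 fell from 8.06 to 1.16 in the second quantification. Spike-in scaling gives lists the percentiles of TMM-scaled counts by arithmetic and is not counted. Of the 10 top gene levels 9 moved by over 1 SD in the second quantification. With n = 2, a level with 1 replicate left out always lies within 1 SD, so those say nothing. At a mean count of at least 100 the mast cell and brown adipocyte lists kept too few members for a value, Sln had none in the second quantification, and differences between the replicates have none with 1 left out. No paired analysis was possible because the series has 1 group. Depth limits genes with few counts, such as Alb, whose ratio has a counting interval from 119 to 26400.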

Other observations

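The tests of heart RNA, fibre makeup and shared reads were chosen after the result was seen, and those of liver RNA, short transcripts and the division among transcripts before it, and the heart genes replaced an earlier set that held atrial genes and genes low in ventricle.

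Myoglobin (Mb), the oxygen store of oxidative fibres, had 510 and 2635 TPM, a log2 ratio of 2.33 for replicate 2 over replicate 1. Tropomyosin Tpm2 had 1132 and 2903 TPM, a log2 ratio of 1.39. Both were chosen after their values were seen. Protein-coding genes held 82.2% and 79.3% of all expected counts, spike-ins included, and lincRNAs 1.62% and 1.69%.

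All 15 slow-type sarcomere genes were higher in replicate 2. Their median log2 ratio was 3.30 by TPM and 3.54 with spike-in scaling, where that of all tested genes was 0.049 and 0.23, and scaling was not tested further because it moves all genes alike. Heart RNA is argued against: the median replicate 2 TPM of Actc1, Tnni3, Myh6 and Tnnt2 was 0.0268 of that of Myl2, Myl3 and Tnnc1. Tnni3 had 1 count in each library, and Actc1 was lower in replicate 2. Going the other way, Myh6 had 5.88 and 73.2 TPM and the heart gene Ryr2 14 and 100 counts. More slow and oxidative fibre in the replicate 2 sample may be the source, with Myh2 at a log2 of 1.90, but that bound was set with the value known. Whether such a difference would come from the animal or from the part of the muscle taken stays open and was not tested.

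Alb and Apob led the genes higher in replicate 2, and liver RNA in that library was tested on 14 other liver genes. Of these, 10 had at least 3 times the depth-scaled counts in replicate 2 and at least 10 counts there, exactly the number set beforehand as the minimum. They had at most 4 counts in replicate 1 and 11 to 57 in replicate 2, with Ttr at 0 and 57, while Serpina1c (0 and 9.3 counts), Hp (290 and 515), Trf (414 and 566) and Cyp2e1 (147 and 302) did not qualify, and 3 of the 16 liver genes had over 100 counts in replicate 1. With these 10 genes, a trace of liver RNA in the replicate 2 library may be the source of the pattern, with Alb at 11.3 TPM there. How it would have come there, at dissection or later, was not tested.

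The quantifications differed for short transcripts, shared genes and isoforms. Genes with 1 transcript and a mean count of at least 100 were compared by length. Under 300 nt, 100% of 57 kept less than 10% of their counts in the second quantification. The share was 60.9% of 87 from 300 to 500 nt, 17.0% of 153 from 500 to 1000 nt and 1.75% of 800 above that. The bounds set beforehand, for the shortest and longest only, were met, so transcripts shorter than the fragments may have gone uncounted. The losses from 500 to 1000 nt were not tested further. Genes already looked at were left out, including mt-Atp8 and mt-Nd4l, which were removed after a first run. Of 1-transcript genes with a posterior SD of at least 5% of the count, 32.8% of 64 differed by 2-fold or more, against 0.908% of 661 with little sharing, so shared reads may account for those. For the division among transcripts, r was 0.149 higher in replicate 1 and 0.164 higher in replicate 2 for genes with 1 transcript than for those with several, between the bounds set beforehand, so its part cannot be told.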
